A study of Homo sapiens with 12 samples.

How the data were processed

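The data are 12 single-cell RNA libraries (10x Genomics Chromium, 3' end) of human adipose cells sorted by CD45, the surface protein that marks blood-derived cells. Per the labels, 3 lean and 3 obese donors each gave 1 CD45 negative and 1 CD45 positive library. The donors are therefore the replicates, and the libraries of 1 donor are paired across the sort. Lean donor 1 and obese donor 1 share a number, and the labels state no other link and no batch. The deposited files hold raw UMI (unique molecular identifier) counts per gene and cell barcode, as whole numbers with no normalization, 1 file per library. Per the labels, the authors made the counts with Cell Ranger on GRCh38 (hg38), with no version stated. Barcodes had already been filtered, to 3628 to 12817 per library. Each file lists the same 33538 gene identifiers with counts. Of these, 82 have no gene name, and 117 were left out of every test: XIST, TSIX, Y-linked genes and some X-linked genes. Symbols and positions on GRCh38 come from GENCODE release 29.

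Depth ranged from 22164097 to 47578171 UMIs per library. UMIs are counted molecules, and replicates differed by more than counting error. Libraries were compared in pairs within a group, over genes with at least 20 counts in the pair together. The lowest chi-square per degree of freedom was 54.5. For these genes in whole libraries, the spread between donors exceeded the error of counting. This was not tested in single classes, which are less deep. For a gene with no UMI in a group, a floor of 3 counts over the pooled group was used as the upper limit, which covers counting error only.

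Cells were kept with at least 200 genes, at least 500 UMIs and at most 20% of UMIs from mitochondrially encoded genes. Per library, the barcodes with the highest Scrublet scores were removed as doublets, at a rate of 0.8% per 1000 barcodes. Scrublet's own threshold was not used: it removed 0 to 23 barcodes in 11 libraries and 1426 in the other. Each CD45 fraction was clustered apart, without batch integration, from counts per 10000 on the log scale, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15). Immunoglobulin and T cell receptor genes were not used to cluster. A cluster took the name of the best of 27 marker lists. A list counted when at least 3 of its markers were detected in at least 10% of a cluster's cells. The cluster stayed unnamed when the list scored under 0.5, when lists of different classes came within 0.1 of each other, when its 10 leading genes held more markers of another class, or when its cells had under 1/3 of their library's median UMIs and no leading gene of the class. These limits on naming were set after the data were examined. Cell types are named as "-like", since the labels give the sort only.

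Cells are not replicates, so UMI counts were summed per library, and per library and class where a library had at least 20 cells of the class. A class needed 2 libraries per phenotype. The sums were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM normalization, a quasi-likelihood F test and Benjamini-Hochberg adjustment, with a threshold of 0.05. Changes are log2 ratios with a standard error (SE) taken as the size of the change divided by the square root of F. Levels are CPM values from edgeR's cpm function on TMM-scaled library sizes, as mean and SD. Lists of genes (22 of pathways and states, and the 27 marker lists, with at least 3 members tested) were tested with camera (limma 3.58.1) at a preset correlation of 0.01. The estimated correlation and fry were alternatives. Camera compares a list with the other genes. Fry asks only whether a list's genes move one way. Shares of cells were tested with an exact two-sided permutation test over the 20 assignments of 6 donors, which cannot give a p below 0.1.

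The comparisons, tests, gene lists, marker lists and the rule for naming genes were fixed before the data were examined. The exception is the macrophage-like class of the CD45 negative libraries, added afterwards. For CD45 positive against negative (with phenotype as a covariate), the rule names PTPRC and the 10 largest increases and 10 largest decreases past the threshold, with a mean of at least 100 CPM. For obese against lean, it names up to 6 increases and 6 decreases past the threshold whose donors do not overlap, with a mean of at least 20 CPM. Where these are fewer than 6 it adds the genes of lowest p up to 6. It also names the 3 members of lowest p of each list that suits the class. Members of a list given to describe it, beyond these, were chosen after their values were seen. Genes whose counts follow a donor's genotype or clone (most classical HLA genes, immunoglobulin, T cell receptor and KIR genes) are never named. For B-like cells, 1 gene that the rule names is not reported here.

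The alternatives were relative log expression size factors, DESeq2 1.42.0, no low-count filter, at most 10% mitochondrial UMIs, at least 1000 UMIs, doublets kept, at least 50 cells per library, principal components centred per library, Leiden resolution 2, a replicate block (by donor across the sort, and by donor number within a fraction), and each library left out in turn. Added after the data were examined were unnamed clusters given the class of their best list, and T-like cells without a heat-shock cluster. The scripts were tested on simulated counts with 200 changed genes per comparison (each of at least 20 CPM), drawn at the depth and spread of the libraries used. Among changes of 4-fold, edgeR recovered 97% for the CD45 negative libraries (15595 genes), 82% for the CD45 positive libraries (14831 genes), 93% for mural-like cells (6518 genes) and 57% for the difference between fractions (16997 genes). Among changes of 2-fold, it recovered 47%, 11%, 48% and 3% for these comparisons. These rates apply to 200 genes changed at once, where Benjamini-Hochberg adjustment is more lenient than with few changed genes. They therefore cannot show that 4-fold changes are absent where few or no genes passed. In progenitor-like cells, 100% of 4-fold changes were recovered in simulation, yet PLA2G2A, with a measured change above 4-fold, did not pass. Unchanged genes were called too. For CD45 negative libraries, CD45 positive libraries, mural-like cells and the difference between fractions, edgeR made 11, 4, 11 and 6 such false calls and DESeq2 44, 53, 4 and 43. False calls numbered 22 by edgeR and 11 by DESeq2 in NK-like cells, and 13 and 30 in T-like cells. Counts by either tool can therefore hold false calls.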

Results

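Single-cell RNA was measured in human adipose cells sorted by CD45, a surface protein of blood-derived cells. There were 4 groups of 3 libraries each: CD45 negative lean, CD45 negative obese, CD45 positive lean and CD45 positive obese. Each of the 6 donors gave 1 library of each fraction. The 12 libraries held 84061 barcodes and 446000712 UMIs. CD45 negative libraries had 22164097 to 47578171 UMIs each, and CD45 positive libraries had 30827527 to 45484508. After filtering and removal of doublets, 32097 CD45 negative cells (median 5282 to 6462 UMIs per library) and 44957 CD45 positive cells (median 3093 to 4365 UMIs) were left. Mitochondrially encoded transcripts took a median of 2.61% to 3.78% of UMIs in CD45 negative libraries, 3.61% to 7.50% in CD45 positive lean libraries and 5.54% to 7.74% in CD45 positive obese libraries.

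The CD45 negative cells fell into 14 clusters and the CD45 positive cells into 23. In CD45 negative libraries, progenitor-like cells (which express collagen and other matrix genes) made up 81.7% ± 7.86 (SD, n = 3) of lean and 73.2% ± 12.3 (SD, n = 3) of obese cells, beside blood endothelial-like, mural-like, macrophage-like and NK-like cells. In CD45 positive libraries, T-like cells made up 54.7% ± 29.1 (SD, n = 3) of lean and 54.9% ± 14.3 (SD, n = 3) of obese cells, beside NK-like, monocyte-like, dendritic-like, macrophage-like, B-like and plasmacytoid dendritic-like cells. There were 6 unnamed clusters: 1 of 2145 CD45 negative cells (6.68%) and 5 of 7647 CD45 positive cells (17.0%). Unnamed cells took 3.20% ± 1.95 of lean and 10.7% ± 5.04 of obese CD45 negative libraries (exact permutation p = 0.1, two-sided, n = 3 and 3). This difference of 7.52 percentage points was 4.85 without obese 2 and 3.06 at Leiden resolution 2, and turned to -1.59 with components centred per library. Unnamed cells took 25.9% ± 14.1 of lean and 9.70% ± 5.32 of obese CD45 positive libraries (exact permutation p = 0.2, n = 3 and 3), a difference of -16.2 points that was -10 without lean 3, -9.78 at resolution 2 and -8.08 with centred components. Centred components also turned the differences in progenitor-like (from -8.49 to 0.616 points) and T-like cells (from 0.263 to -1.85 points).

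CD45 positive against CD45 negative libraries asked what the sort separated. PTPRC, the gene of CD45 (ENSG00000081237, protein coding, GRCh38 chromosome 1, 198638457 to 198757476), rose by 6.31 ± 0.64 on the log2 scale (SE, n = 6 and 6, adjusted p = 2.71e-06), from 21.8 ± 24.5 CPM to 1545 ± 517 CPM (SD). T cell receptor complex genes rose most among the named genes: CD3D by 8.04 ± 0.69 and CD3E by 7.23 ± 0.82. With them rose CD2, IL7R (the interleukin 7 receptor), CD48, the chemokine CCL5 and the cytotoxic effectors PRF1 (perforin) and GZMH (a granzyme), by 6.21 to 7.14. The largest decreases among the named genes were those of PLA2G2A and of matrix genes. PLA2G2A, a secreted phospholipase (ENSG00000188257, protein coding, chromosome 1, 19975431 to 19980416), changed by -10.43 ± 1.18, from 666 ± 566 CPM to 0.415 CPM. PRG4 (lubricin) changed by -10.27 ± 0.76, the microfibril gene MFAP5 by -10.08 ± 1.11 and the type I collagen gene COL1A2 by -9.58 ± 1.39.

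**Figure D1:**
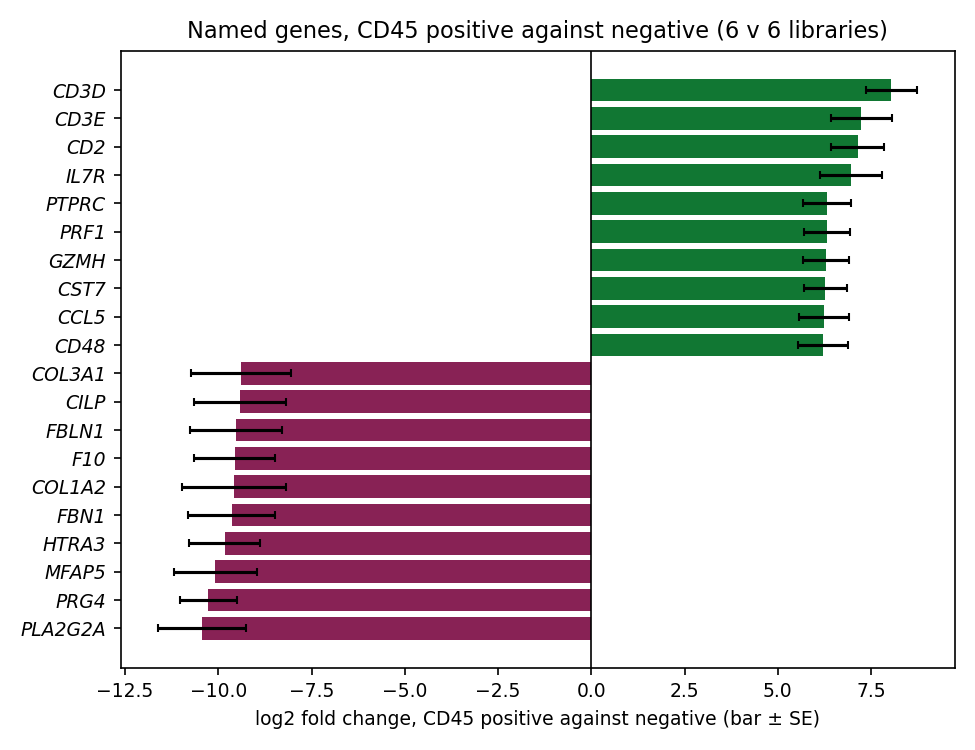
Bars give the log2 fold change of the named genes in CD45 positive against CD45 negative libraries (6 and 6), with whiskers of ± SE. CD3D stands at 8.04 and PLA2G2A at -10.43.

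Gene groups followed the sort. All 11 cytotoxicity genes rose (median log2 change 5.90, adjusted p = 0.000459), as did 10 of 10 T cell checkpoint and activation genes (median 5.38), 9 of 9 MHC class II presentation genes (median 3.92) and 6 of 7 B cell markers (median 3.62). Of 18 collagen and matrix genes, 15 fell and 1 rose (median -8.14, adjusted p = 0.000459). All 15 mural markers fell (median -6.07), with 12 of 13 progenitor markers (median -9.23) and 10 of 11 blood endothelial markers (median -4.05). Macrophage markers did not pass (median 1.42, adjusted p = 0.637). All 10 mitochondrially encoded transcripts rose (median 0.87, adjusted p = 0.00814). In total 24 of 44 lists passed, and none did with an estimated correlation (lowest adjusted p = 0.441 with an estimated correlation). Adjusted over the list alone, 11 cytotoxicity genes and 16 collagen and matrix genes passed. Of 16084 genes tested, 6306 rose and 6379 fell, and 60.4% had CD45 positive and negative libraries that did not overlap.

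Shares of cells were compared between obese and lean donors by exact two-sided permutation tests, which with 3 against 3 cannot give a p below 0.1, and by chance 10% of such comparisons have groups that do not overlap. Monocyte-like cells were 3.68% ± 3.98 (SD, n = 3) of lean and 12.4% ± 3.60 (SD, n = 3) of obese CD45 positive libraries, without overlap (exact p = 0.1). With unnamed clusters given the class of their best list they were 5.93% and 14.2%, and overlapped (exact p = 0.2, n = 3 and 3). Macrophage-like cells were 6.38% ± 5.89 of lean and 1.88% ± 1.15 of obese CD45 negative libraries, without overlap (exact p = 0.1, n = 3 and 3). Without lean 1 the lean mean was 2.99%, and the difference went from -4.50 to -1.10 percentage points. In CD45 positive libraries, macrophage-like cells were 2.19% ± 1.94 of lean and 1.49% ± 1.05 of obese cells, and overlapped (exact p = 0.6, n = 3 and 3). The sort was meant to keep blood-derived cells out of the CD45 negative fraction. Whether their share there follows how cleanly each library was sorted was not tested. Within T-like cells, the regulatory T-like cluster (led by CD177, with the regulatory T cell genes FOXP3 and CTLA4) was 2.15% ± 1.73 in lean and 7.15% ± 1.57 in obese libraries (exact p = 0.1, n = 3 and 3). Type 1 dendritic-like cells were 0.455% ± 0.347 of lean and 1.18% ± 0.380 of obese CD45 positive cells (exact p = 0.1, n = 3 and 3), without overlap. Blood endothelial-like cells were 3.69% ± 1.70 of lean and 8.26% ± 5.69 of obese CD45 negative cells, and these overlapped (exact p = 0.3, n = 3 and 3), with a difference of 4.58 points that was 1.36 without obese 2. Of all clusters' shares of their library, 3 of 14 in CD45 negative and 5 of 23 in CD45 positive libraries did not overlap. No cluster met the rule for lipid-associated macrophages, so their share has no value. No share passed after adjustment.

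**Figure D2:**
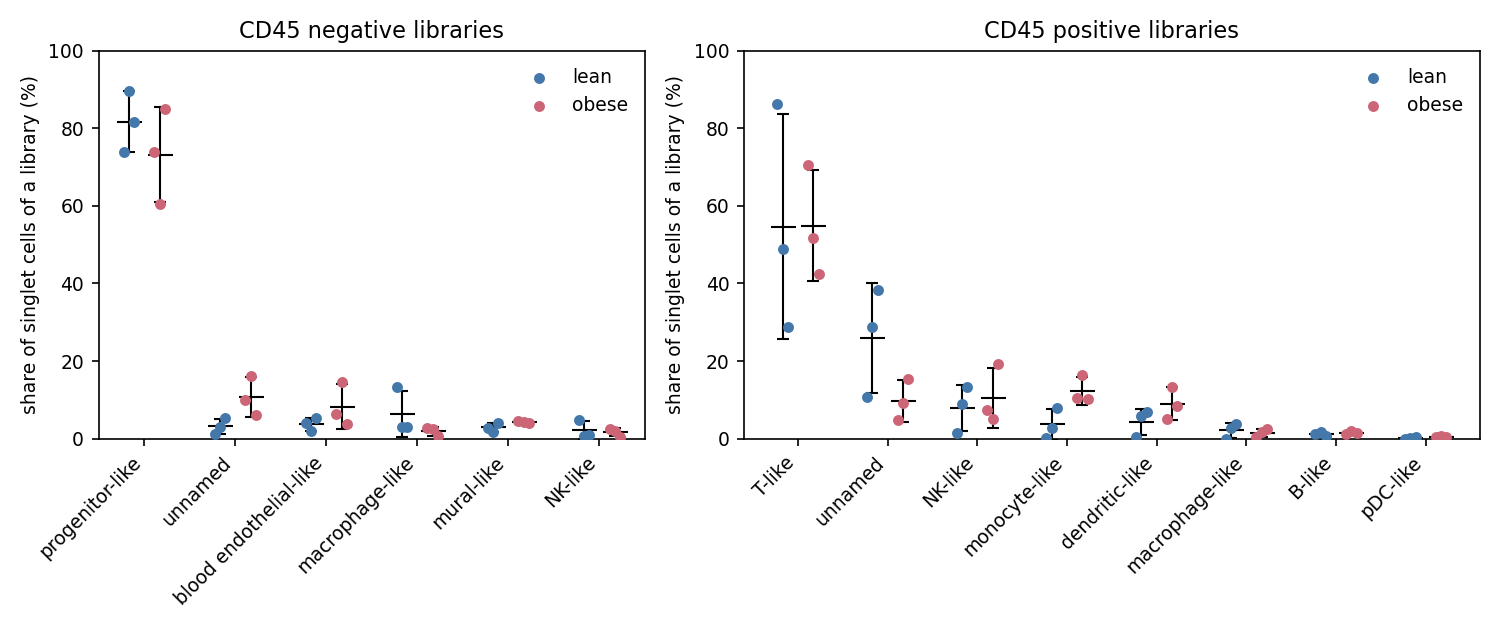
Points give each library's share of singlet cells (%) in each class, for lean and obese donors (3 each per fraction), with mean and SD. Monocyte-like cells average 3.68% in lean and 12.4% in obese CD45 positive libraries.

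Obese against lean was tested within each fraction and cell class, in 12 comparisons. Only 7 genes passed in all. The 3 that can be named were NNMT and PLA2G2A in mural-like cells and CD83 in NK-like cells. The other 4 calls were in HLA genes, whose counts can follow a donor's genotype. Of 340 list tests 70 passed, and none held with an estimated correlation (lowest adjusted p = 0.369 with an estimated correlation). By fry, 2 held. The interferon response list had a median above 0 in 12 of 12 comparisons and passed, upward, in 7, of which 5 ended when 1 library was left out (whole CD45 positive libraries, mural-like, dendritic-like, T-like and B-like cells). These comparisons reuse the same 6 donors, and whole libraries contain the cells of their classes, so they are not 12 independent observations. Mitochondrially encoded transcripts passed upward in 6 and downward in 1.

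**Figure D3:**
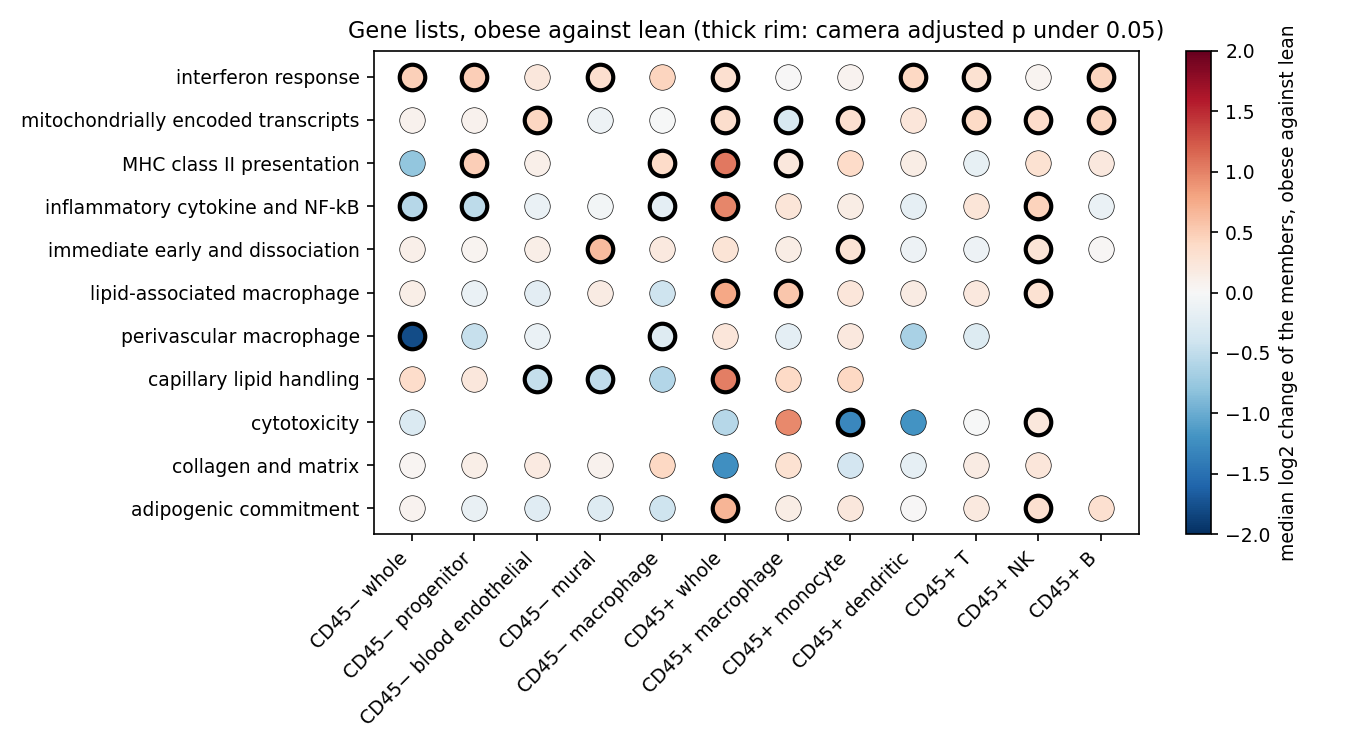
Dots give the median log2 change of each list's members, obese against lean, in each fraction and class, and a thick rim marks a camera adjusted p under 0.05. Blank positions had fewer than 3 members tested. The interferon response row runs from 0.00 to 0.49.

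In progenitor-like cells of obese donors, interferon response genes were higher together. All 14 members of the list had a log2 change above 0 (median 0.49, adjusted p = 2.14e-07; adjusted p = 0.655 with an estimated correlation), and no single member passed, also when adjusted over the list alone. Members included ISG15, a ubiquitin-like protein induced by interferon (0.79 ± 0.24, from 15.5 ± 5.2 to 26.8 ± 4.11 CPM; SE and SD, n = 3 and 3), IFIT3 (0.59 ± 0.20) and IFI44L (0.85 ± 0.29). The call held without each of the 6 libraries in turn. Blood endothelial markers also had 9 of 10 members above 0 (median 0.91, adjusted p = 3.85e-06; adjusted p = 0.642 with an estimated correlation). These are genes of another cell type, which took 3.69% of lean and 8.26% of obese CD45 negative libraries. Whether its free RNA gave these UMIs was not tested. The list of 7 MHC class II presentation genes passed upward (median 0.50, adjusted p = 0.0154; adjusted p = 0.906 with an estimated correlation), but not without CD45 negative lean 3 (0.31, adjusted p = 0.143) or obese 1 (adjusted p = 0.0748). Of its genes 5 were above 0, and 2 passed adjusted over the list alone. Inflammatory cytokine and NF-kB genes passed downward (12 of 16 below 0, median -0.52, adjusted p = 0.0154; adjusted p = 0.906 with an estimated correlation), with none passing adjusted over the list alone, but not without lean 1 (adjusted p = 0.113), lean 3 (adjusted p = 0.0533) or obese 3 (adjusted p = 0.0735). Without obese 1 that median was -0.34.

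Among single genes in progenitor-like cells, PLA2G2A had the highest level of the named genes of lowest p: 301 ± 89.3 CPM in lean and 1259 ± 756 CPM in obese libraries (log2 2.06 ± 0.42, n = 3 and 3, adjusted p = 0.887). HTATIP2 (1.46 ± 0.19), the apolipoprotein gene APOL1 (0.85 ± 0.12) and the cation channel gene MCOLN3 (-0.74 ± 0.11) had lower p, with lean and obese libraries apart, and did not pass. TIMP1, an inhibitor of matrix proteases, was at 683 ± 96.4 CPM in lean and 1041 ± 172 CPM in obese libraries. By edgeR 0 of 14772 genes passed. There were 788 at an unadjusted p under 0.05 and 28 by DESeq2, and 10.8% of genes had libraries that did not overlap. Without lean 3, 1 gene passed. The count of lists was 4, and 9 without lean 2. In 1 obese library, 2506 cells of 1 progenitor-like cluster (led by PHLDA1) made up most of that cluster's 3223. The cluster took 1.33% ± 1.27 of lean and 24.6% ± 26.4 of obese progenitor-like cells (exact permutation p = 0.1, n = 3 and 3). Other clusters were uneven too: that led by SOD2 took 23.9% ± 27.9 and 10.8% ± 9.42 of these cells (exact permutation p = 0.7, n = 3 and 3, up to 56.1% in a lean library), and that led by PTX3 14.3% ± 19.4 and 3.37% ± 2.61 (exact permutation p = 0.6, n = 3 and 3, 74.3% of it from 1 library).

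Blood endothelial-like cells of obese donors had lower capillary lipid-handling genes. All 10 members were below 0 (median -0.48, adjusted p = 0.000263; adjusted p = 0.584 with an estimated correlation), and the call held without each library in turn. FABP4, a fatty acid binding protein, was at 23584 ± 8361 CPM in lean and 15750 ± 981 CPM in obese libraries (-0.58 ± 0.22; SE and SD, n = 3 and 3). RBP7, a retinol binding protein, went from 4410 CPM to 2601 CPM (-0.76 ± 0.20), and GPIHBP1, which anchors lipoprotein lipase to capillaries, had -0.62 ± 0.24. Adjusted over the list alone, 5 of the 10 passed. The list was not particular to these cells: it also passed downward in mural-like cells and upward in whole CD45 positive libraries. ACKR1, a chemokine receptor of venules, was at 324 ± 277 CPM in lean and 806 ± 89.7 CPM in obese libraries (1.30 ± 0.53, adjusted p = 0.683). In the same cells, mitochondrially encoded transcripts were higher (10 of 10 above 0, median 0.43, adjusted p = 0.000263; adjusted p = 0.404 with an estimated correlation), and 6 passed adjusted over the list alone. Of 7465 genes, 0 passed by edgeR, with 495 at an unadjusted p under 0.05 and 6 by DESeq2; 1 passed without lean 1 and 6 without obese 3. The 2 lists became 6 without lean 2, lean 3 or obese 1, and 4 without obese 2 or obese 3.

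In mural-like cells (pericytes and smooth muscle), NNMT, nicotinamide N-methyltransferase (ENSG00000166741, protein coding, chromosome 11, 114257787 to 114313285), rose from 50.6 ± 12.6 CPM in lean to 143 ± 11 CPM in obese libraries (log2 1.52 ± 0.24; SE and SD, n = 3 and 3, adjusted p = 0.0284). PLA2G2A had 0 UMIs in lean and 118 UMIs in obese mural-like cells (39.3 ± 13.6 CPM, adjusted p = 0.00601). Against a floor of 3 UMIs over the 1564439 UMIs of the pooled lean group, it was at least 19.6-fold higher. PLA2G2A was also abundant in progenitor-like cells of the same libraries, whose free RNA can reach other cells. It fell outside the rule for naming genes and was chosen after its values were seen.

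The NNMT call ended with doublets kept (1.34, adjusted p = 0.103), with a replicate block (adjusted p = 0.0779), and without lean 2 (adjusted p = 0.132), lean 3 (adjusted p = 0.228), obese 1 (adjusted p = 0.0778) or obese 3 (adjusted p = 0.0721). The PLA2G2A call ended with doublets kept (2.62, adjusted p = 0.328) and without lean 3 (adjusted p = 0.0556).

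Immediate early genes, which respond to stimulation and to tissue dissociation, were higher in mural-like cells of obese donors: 14 of 14 were above 0 (median 0.63, adjusted p = 1.52e-08; adjusted p = 0.827 with an estimated correlation), and 8 passed adjusted over the list alone. FOS went from 2676 ± 443 to 5176 ± 664 CPM, JUN from 2080 to 3588 CPM and ATF3 from 617 to 1085 CPM (n = 3 and 3). This call held without each library in turn. Progenitor markers passed upward in these cells (9 of 10 above 0, median 0.27, adjusted p = 0.0149; adjusted p = 0.827 with an estimated correlation), but not without lean 3 (adjusted p = 0.470), and the median was 0.86 without lean 1 and 0.42 without lean 2. Capillary lipid-handling genes passed downward (6 of 7 below 0, median -0.50, adjusted p = 0.0209; adjusted p = 0.915 with an estimated correlation), with none passing adjusted over the list alone, but not without lean 1 (adjusted p = 0.0748), lean 3 (adjusted p = 0.239) or obese 1 (adjusted p = 0.335). Interferon response genes passed upward (9 of 9 above 0, median 0.33, adjusted p = 0.0232; adjusted p = 0.827 with an estimated correlation), with none passing adjusted over the list alone, but not without lean 1 (adjusted p = 0.0755), lean 2 (0.60, adjusted p = 0.213) or obese 1 (0.16, adjusted p = 0.335), and the median was 0.58 without lean 3. MGP, matrix Gla protein, was at 913 ± 83.6 CPM in lean and 1828 ± 57.1 CPM in obese libraries (1.00 ± 0.21, adjusted p = 0.227). Of 6824 genes, 2 passed and 472 had an unadjusted p under 0.05. The count was 3 without lean 1 or obese 2, 1 without lean 2 or obese 3, and 0 without lean 3. Of 19 lists 4 passed, and 2 without obese 1.

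**Figure D4:**
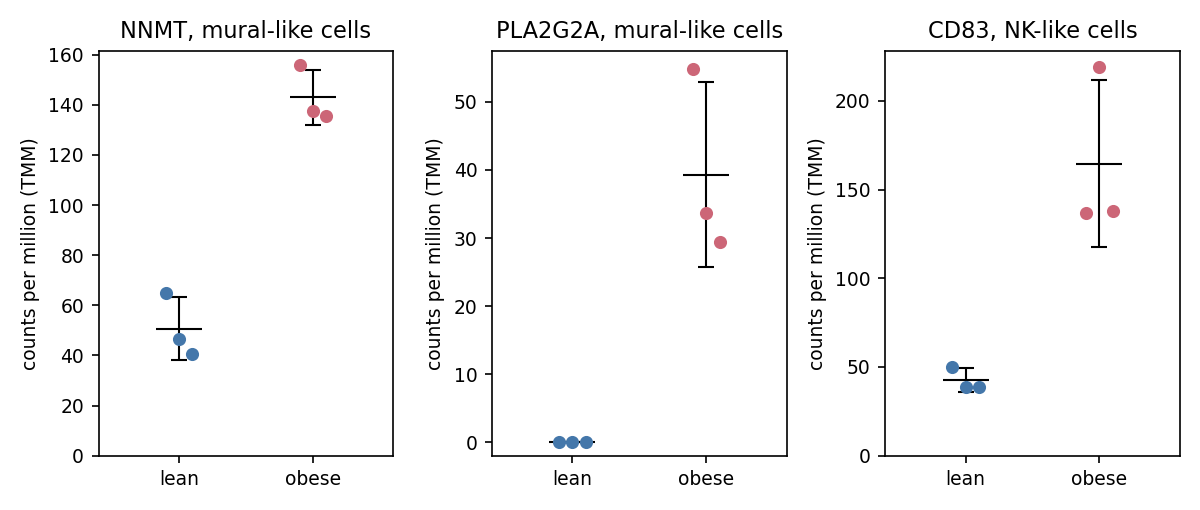
Points give CPM on TMM-scaled library sizes for the 3 named genes that passed, per lean and obese library (3 each), with mean and SD. Lean libraries had no PLA2G2A UMI in mural-like cells.

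NK-like cells of obese donors had more CD83, an activation marker of the immunoglobulin family (ENSG00000112149, protein coding, chromosome 6, 14117256 to 14136918). It rose from 42.5 ± 6.60 to 165 ± 47.1 CPM (log2 1.98 ± 0.22; SE and SD, n = 3 and 3, adjusted p = 0.00471). The call ended without lean 2 (1.92, adjusted p = 0.0872) and without lean 3 (1.92, adjusted p = 0.0761). Whether free RNA of other classes gave part of the CD83 UMIs was not tested. The transcription factor gene GATA3 (65.5 to 115 CPM), the lymphotoxin gene LTB (32.8 to 72.0 CPM) and RRAD (9.87 to 40.8 CPM, adjusted p = 0.0830) were apart in level between lean and obese libraries and did not pass. All 5 innate lymphoid cell (ILC) markers tested were above 0 (median 0.78, adjusted p = 0.0193; adjusted p = 0.369 with an estimated correlation), with 1 passing adjusted over the list alone, and the median was 1.30 without lean 1. The ILC-like cluster made up 2.65% ± 1.18 of lean and 7.09% ± 1.79 of obese NK-like cells (exact permutation p = 0.1, n = 3 and 3). The other clusters of this class also had unequal shares: the cluster led by CSF2 took 14.5% ± 9.92 of lean and 25.5% ± 10.9 of obese NK-like cells, with 61.3% of it from 1 library, and the cluster led by MYOM2 took 82.9% ± 11.1 and 67.4% ± 12.1 (exact permutation p = 0.2 for each, n = 3 and 3). Inflammatory cytokine and NF-kB genes had 9 of 11 members above 0 (median 0.45, adjusted p = 0.0124; adjusted p = 0.369 with an estimated correlation). The ILC and inflammatory calls held without each library in turn. Mitochondrially encoded transcripts also passed upward (median 0.37, adjusted p = 0.00837; adjusted p = 0.449 with an estimated correlation), but not without lean 1 (0.15, adjusted p = 0.110), with 0.60 without lean 3. Immediate early and dissociation genes passed upward too (13 of 14 above 0, median 0.28, adjusted p = 0.0193; adjusted p = 0.446 with an estimated correlation), with none passing adjusted over the list alone, but not without lean 3 (0.18, adjusted p = 0.217) or obese 2 (0.13, adjusted p = 0.225), with 0.46 without obese 1. Of 9056 genes 1 passed; there were 0 without lean 2 or lean 3 and 2 without obese 1 or obese 3. Of 25 lists 9 passed, and 5 without obese 1 or obese 2. Among the 9, markers of cycling cells passed upward, but not without lean 2 (0.58, adjusted p = 0.0539) or obese 3 (0.38, adjusted p = 0.130). The adipogenic commitment, lipid-associated macrophage, cholesterol synthesis and cytotoxicity lists passed upward too. Each of these calls ended in 4 of the 6 fits that left out 1 library.

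In T-like cells, regulatory T cell markers were higher in obese donors: 7 of 7 were above 0 (median 0.47, adjusted p = 0.000664; adjusted p = 0.526 with an estimated correlation), and 3 passed adjusted over the list alone. The call held without each library in turn, with a median of 0.80 without lean 3. ILC markers also passed upward in T-like cells, with medians of 0.27 to 0.92 with 1 library left out. That call ended without lean 1 (0.27, adjusted p = 0.165) or obese 3 (0.52, adjusted p = 0.0740). The clusters of this class had unequal shares in lean and obese libraries, which such changes include: 2.15% and 7.15% for the regulatory T-like cluster, and 8.71% ± 3.10 and 15.4% ± 4.77 for the cluster led by CCR6, with CCR7 (exact permutation p = 0.1 for each, n = 3 and 3). The heat-shock cluster, led by MT1X, had 93.1% of its cells from 1 lean library, where it was 16.1% of T-like cells, against a mean of 0.0389% in obese libraries. CTLA4, an inhibitory receptor, was at 64.8 ± 8.58 CPM in lean and 108 ± 16.6 CPM in obese libraries (0.73 ± 0.15; SE and SD, n = 3 and 3). The co-stimulatory receptor gene TNFRSF4 (OX40) had the lowest p of all genes (28.3 ± 1.12 to 55.0 ± 6.35 CPM, log2 0.96 ± 0.12, adjusted p = 0.216). CCR7, a lymph node homing receptor, had 0.72 ± 0.17. The list of early progenitor genes had 3 members here, PI16 (1.34), CD55 (0.36) and DPP4 (0.19). CD55 is a complement regulator and DPP4 a peptidase, both also found on T cells. This list passed upward (median 0.36, adjusted p = 0.0101; adjusted p = 0.526 with an estimated correlation).

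Interferon response genes passed upward in T-like cells (10 of 14 above 0, median 0.30, adjusted p = 0.00713; adjusted p = 0.647 with an estimated correlation), with 4 passing adjusted over the list alone, but not without lean 2 (0.19, adjusted p = 0.203) or obese 2 (0.12, adjusted p = 0.0503). XAF1 had 0.77 ± 0.15 and IFI6 0.50 ± 0.12. Mitochondrially encoded transcripts were higher in the same cells (10 of 10 above 0, median 0.40, adjusted p = 0.00354; adjusted p = 0.647 with an estimated correlation), but not without lean 1 (0.20, adjusted p = 0.116), with 0.26 without lean 2 and 0.82 without lean 3. Of 12101 genes, 0 passed by edgeR, with 1042 at an unadjusted p under 0.05 and 33 by DESeq2. Without lean 1 the count was 2, and 1 without obese 1 or obese 3. Of 34 lists 7 passed, 3 without lean 1 and 11 without lean 3.

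Monocyte-like cells of obese donors had lower cytotoxicity transcripts. All 9 were below 0 (median -1.30, adjusted p = 6.74e-09; adjusted p = 0.692 with an estimated correlation), 5 passed adjusted over the list alone, and the call held without each library in turn. These are lymphocyte genes, and free RNA of lymphocytes gives UMIs in other cells. Their summed level was 295 ± 33.4 CPM in lean and 88.4 ± 55.7 CPM in obese monocyte-like cells, against 5075 and 2959 CPM in whole CD45 positive libraries (SD, n = 3 and 3). Markers of CD8 T cells (7 of 7 below 0, median -0.93, adjusted p = 3.07e-06) and NK cells (7 of 9 below 0, median -1.30, adjusted p = 0.0021) were lower too, each with adjusted p = 0.692 with an estimated correlation, and both calls held without each library in turn. Adjusted over the list alone, 2 and 5 of these passed. The CD8 T median was -0.57 without lean 1, -1.79 without lean 3 and -1.42 without obese 1, and the NK median -0.83 without lean 2. Macrophage markers passed upward (10 of 12 above 0, median 0.39, adjusted p = 0.00268; adjusted p = 0.692 with an estimated correlation), with a median of 1.14 without lean 3 and 0.23 without obese 2. OLR1, a receptor for oxidized lipoprotein, was at 450 ± 133 CPM in lean and 872 ± 115 CPM in obese libraries (0.98 ± 0.22, adjusted p = 0.447), and RETN (resistin) at 81.8 ± 88.3 and 20.2 ± 2.57 CPM (adjusted p = 0.447). Immediate early and dissociation genes passed upward (13 of 14 above 0, median 0.29, adjusted p = 0.0297), but not without lean 1 (0.15, adjusted p = 0.570), lean 3 (adjusted p = 0.0884) or obese 2 (adjusted p = 0.192). So did mitochondrially encoded transcripts (10 of 10 above 0, median 0.32, adjusted p = 0.0401), but not without lean 1 (0.16, adjusted p = 0.468), lean 2 (adjusted p = 0.327) or obese 3 (0.21, adjusted p = 0.139), with 0.69 without lean 3. Both had adjusted p = 0.692 with an estimated correlation, and none of their genes passed adjusted over the list alone. Of 10562 genes 1 passed, an HLA gene. The count was 3 without lean 1 or obese 1, 0 without lean 2 or obese 2, 2 without lean 3 and 5 without obese 3. The 6 lists of 31 that passed became 10 without obese 3. Lean 1 had only 24 monocyte-like cells.

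In dendritic-like cells, interferon response genes had 11 of 12 members above 0 in obese donors (median 0.41, adjusted p = 0.00391; adjusted p = 0.471 with an estimated correlation), with 1 passing adjusted over the list alone. ISG15 was at 38.9 ± 8.12 CPM in lean and 66.0 ± 6.90 CPM in obese libraries (0.84 ± 0.18, n = 3 and 3). The call ended without lean 2 (adjusted p = 0.0788), lean 3 (0.63, adjusted p = 0.0829) or obese 2 (adjusted p = 0.0919). C1QA, a complement component made by macrophages, was at 11.7 ± 8.69 and 46.9 ± 0.910 CPM (adjusted p = 0.124). Of 10025 genes, 0 passed by edgeR, with 659 at an unadjusted p under 0.05 and 11 by DESeq2. Without lean 1 or obese 3 the count was 1, and 2 without lean 3. The 1 list of 30 became 5 without lean 1, 0 without lean 2 or obese 2, 2 without lean 3 and 6 without obese 3.

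Macrophage-like cells of CD45 positive libraries could be compared in 2 lean and 3 obese libraries, since lean 1 had 1 such cell. Lipid-associated macrophage genes had 9 of 9 members above 0 in obese donors (median 0.56, adjusted p = 0.00117; adjusted p = 0.750 with an estimated correlation), with 2 passing adjusted over the list alone. TREM2, a lipid-sensing receptor, was at 1.99 ± 2.81 CPM in lean and 22.4 ± 14.5 CPM in obese libraries (3.10 ± 0.95, n = 2 and 3, adjusted p = 0.724), and the fatty acid binding protein FABP5 at 149 and 477 CPM. This class held 135044 to 1083240 UMIs per library, so the lean TREM2 level rests on few UMIs and its fold change is imprecise. The list's call ended without obese 2 (0.21, adjusted p = 0.120). Leaving out lean 2 or lean 3 leaves 1 lean library, so only medians are given for these fits. The list's median was 0.15 without lean 2 and 2.91 without lean 3. Monocyte markers were higher in the same cells (7 of 8 above 0, median 1.04, adjusted p = 0.000523; adjusted p = 0.750 with an estimated correlation), with 2 passing adjusted over the list alone and medians of 0.56 without lean 2, 1.68 without lean 3 and 0.44 without obese 1. That call ended without obese 2 (0.50, adjusted p = 0.0712). Mitochondrially encoded transcripts were lower (median -0.33, adjusted p = 0.0403; adjusted p = 0.768 with an estimated correlation), but not without obese 1 (adjusted p = 0.0615) or obese 2 (-0.17, adjusted p = 0.687). Their median was -0.55 without obese 3. With 1 lean library left, it was -0.54 without lean 2 and -0.10 without lean 3. Of 7320 genes 1 passed, an HLA gene. The count was 3 without obese 2, 4 without obese 3 and 2 without obese 1. The 4 lists of 21 became 0 without obese 2.

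B-like cells gave 1 call among 4030 genes, an HLA gene, which became 4 without lean 2, 0 without lean 3 and 2 without obese 2. Interferon response genes had 5 of 5 members above 0 in obese donors (median 0.44, adjusted p = 0.0308; adjusted p = 0.614 with an estimated correlation), with ISG15 at 38.1 ± 6.62 CPM in lean and 92.2 ± 10.1 CPM in obese libraries (1.28 ± 0.28, n = 3 and 3). The cytokine gene IL6 was at 58.3 ± 22.8 and 199 ± 96.7 CPM (adjusted p = 0.322). Mitochondrially encoded transcripts were higher (median 0.42, adjusted p = 0.000974; adjusted p = 0.658 with an estimated correlation). The interferon call ended without lean 1 (adjusted p = 0.188), lean 2 (0.67, adjusted p = 0.206) or obese 3 (adjusted p = 0.161), and the mitochondrial call without lean 1 (0.19, adjusted p = 0.307) or obese 3 (adjusted p = 0.0522), with 0.80 without lean 3. The 2 lists of 14 became 0 without lean 1 or obese 3 and 1 without lean 2.

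Whole libraries mix these classes, so their changes include the shares of cells. In CD45 negative libraries, interferon response genes again had 14 of 14 members above 0 in obese donors (median 0.48, adjusted p = 2.03e-07; adjusted p = 0.825 with an estimated correlation), and perivascular macrophage genes had 10 of 10 below 0 (median -1.78, adjusted p = 0.000211; adjusted p = 0.825 with an estimated correlation). Both calls held without each library in turn, but the perivascular median was -0.77 without lean 1. Markers of whole cell types passed as well, each with adjusted p = 0.825 with an estimated correlation and no gene passing adjusted over the list alone. Upward went blood endothelial (median 1.11, adjusted p = 0.00039) and mural markers (0.46, adjusted p = 0.000426), downward macrophage (-1.56, adjusted p = 0.00158), monocyte (-1.37, adjusted p = 0.0187) and CD4 T markers (-1.04, adjusted p = 0.0292). Without lean 1 the mural (adjusted p = 0.0534), macrophage (-0.40, adjusted p = 0.0704), monocyte (-0.39, adjusted p = 0.186) and CD4 T calls (0.06, adjusted p = 0.453) ended. So did the macrophage (adjusted p = 0.102), monocyte (adjusted p = 0.0799) and CD4 T calls (adjusted p = 0.246) without obese 3. Without obese 2 the endothelial (0.30, adjusted p = 0.124) and CD4 T calls (adjusted p = 0.0577) ended, and the CD4 T median was -1.69 without lean 3. Venous and activated endothelium genes (median 1.01), lysosome genes (-0.13) and inflammatory cytokine and NF-kB genes (-0.57) were the rest of the 10 lists called, and each of these calls ended without at least 1 library. APOC1 was at 56.2 ± 1.5 CPM in lean and 99 ± 5.63 CPM in obese libraries (0.82 ± 0.10, n = 3 and 3, adjusted p = 0.851). By edgeR 0 of 15894 genes passed, with 678 at an unadjusted p under 0.05 and 22 by DESeq2; 2 passed without lean 1 and 1 without obese 2.

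In whole CD45 positive libraries, obese donors had higher blood endothelial markers (10 of 11 above 0, median 2.05, adjusted p = 2.40e-06), MHC class II presentation genes (9 of 9, median 1.05, adjusted p = 0.00201), inflammatory cytokine and NF-kB genes (16 of 17, median 0.98, adjusted p = 0.00113) and mitochondrially encoded transcripts (10 of 10, median 0.35, adjusted p = 0.00357). Each call held without each library in turn, and each had an adjusted p = 0.603 with an estimated correlation. Adjusted over the list alone, 6 of the endothelial markers passed and none of the other 3 lists' genes. No CD45 positive cluster was named blood endothelial-like, and whether free RNA or a few such cells gave these UMIs was not tested. Medians moved for MHC class II (0.59 without lean 1, 0.68 without obese 2), inflammatory (1.82 without lean 3) and mitochondrial genes (0.69 without lean 3). Capillary lipid-handling genes passed upward (9 of 9 above 0, median 1.02, adjusted p = 0.00113; adjusted p = 0.603 with an estimated correlation), with 1.83 without lean 3. Of the 14 lists that passed, only progenitor markers passed downward (12 of 13 below 0, median -3.83, mean -3.00, adjusted p = 0.0157; adjusted p = 0.603 with an estimated correlation). That call ended without lean 2 (-1.31, adjusted p = 0.0659), a library that stood above the others in several matrix genes, or obese 3 (adjusted p = 0.0686). No gene of these 2 lists passed adjusted over the list alone. Markers of antigen-presenting cells passed upward beside the MHC class II genes: cDC2 (6 of 6 above 0, median 1.41, adjusted p = 0.00944; adjusted p = 0.603 with an estimated correlation), macrophage (0.85, adjusted p = 0.00893; adjusted p = 0.610 with an estimated correlation) and pDC markers (0.73, adjusted p = 0.0323; adjusted p = 0.603 with an estimated correlation), none with a gene passing adjusted over the list alone. The cDC2 call held without each library in turn (0.86 without lean 1). The macrophage call (0.28, adjusted p = 0.378) and the pDC call (0.38, adjusted p = 0.126) ended without lean 1, and their medians were 1.78 and 1.29 without lean 3. Interferon response genes (median 0.32, adjusted p = 0.00717; adjusted p = 0.603 with an estimated correlation, 1 passing adjusted over the list alone) did not pass without lean 2 (adjusted p = 0.0707) and had 0.49 without lean 3. HLA-DPA1, an MHC class II chain, was at 912 ± 597 CPM in lean and 2801 ± 1272 CPM in obese libraries. TGFBR3, a co-receptor for TGF-beta, was at 60.1 ± 3.58 and 32.8 ± 2.03 CPM (-0.87 ± 0.12, n = 3 and 3, adjusted p = 0.472). By edgeR 0 of 15137 genes passed, with 1591 at an unadjusted p under 0.05 and 106 by DESeq2, and 21.1% of genes had libraries that did not overlap, where chance gives 10%.

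The difference between fractions in the effect of obesity was tested as an interaction over all 12 libraries. By edgeR 0 of 17557 genes passed, with 1116 at an unadjusted p under 0.05 and 6 by DESeq2, and 1 passed without CD45 positive lean 1. With each donor as a block across its libraries, 0 genes and 12 lists passed. TGFBR3 (-1.01 ± 0.21) and DIP2A (-1.02 ± 0.22) had the lowest p (adjusted p = 0.707). Of 45 lists 13 passed, and 8 without CD45 positive lean 1. Inflammatory cytokine and NF-kB genes moved upward in CD45 positive relative to CD45 negative libraries (17 of 18 above 0, median 1.48, adjusted p = 6.91e-06), with MHC class II presentation genes (9 of 9, median 1.89, adjusted p = 0.000342) and macrophage markers (10 of 12, median 2.45, adjusted p = 0.000116). These calls held without each library in turn, with adjusted p = 0.774 with an estimated correlation. Without CD45 negative lean 1 the MHC class II median was 0.81 and the macrophage median 1.28. Whole libraries were compared, so these differences include the shares of cells. Macrophage-like cells were 6.38% of lean and 1.88% of obese CD45 negative libraries, and whether this follows the sort was not tested. Monocyte-like cells were 3.68% of lean and 12.4% of obese CD45 positive libraries.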

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

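The tests of RNA from progenitor-like cells and from lymphocytes, and the tests that leave out a library or donor, were chosen after the result was seen. The tests of NNMT from blood endothelial-like cells and of interferon transcripts from other classes were set before theirs was.

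Single libraries stood far from the other 5 of their fraction in 9 of 40 groups of 6 values. Each group held 1 gene named for CD45 positive against negative. All flags were in CD45 negative lean 1 or CD45 positive lean 2. Chance flags about 1 group in 20, but the groups reuse the same libraries and are not independent, so the count was not tested. CD45 negative lean 1 had CD3D at 3.78 CPM (others 0.17 to 0.75), CD3E at 9.23 CPM (others 0.47 to 1.87) and MFAP5 at 636 CPM (others 1482 to 1982). CD45 positive lean 2 had these genes above the others, several of them matrix genes: CILP 3.31 CPM (others at most 0.47), F10 1.84 CPM (at most 0.11), FBLN1 14.7 CPM (at most 1.74), FBN1 8.13 CPM (at most 0.69), HTRA3 2.07 CPM (at most 0.29) and MFAP5 9.71 CPM (at most 1.05). Over whole libraries, CD45 positive lean 1 stood furthest from its replicates. Its log2 CPM correlated at 0.952 with lean 2 and 0.929 with lean 3, against 0.979 to 0.988 in the other pairs of CD45 positive libraries within a group. It also had the most barcodes (12817) and the lowest median UMIs (3093) of its fraction.

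Changes in whole libraries include the shares of cells. In them, a difference between fractions in the effect of obesity, tested as an interaction, passed for 13 lists. Their median log2 changes were 0.67 for adipogenic commitment, 1.48 for inflammatory cytokine and NF-kB, 0.89 for lipid-associated macrophage, 2.21 for perivascular macrophage, 1.89 for MHC class II presentation, 0.70 for lysosome, 0.26 for mitochondrially encoded transcripts, -3.96 for progenitor markers (mean -3.03), 0.57 for blood endothelial markers, 2.45 for macrophage markers, 2.46 for monocyte markers, 1.44 for cDC1 markers and 2.29 for cDC2 markers. With an estimated correlation each had an adjusted p = 0.774. Leaving out 1 library ended 8 of these calls and moved their medians. For adipogenic commitment (medians 0.36 to 0.92) it was CD45 negative lean 1 (adjusted p = 0.0652) or obese 1 (0.0918), or CD45 positive lean 1 (0.216) or obese 2 (0.145). For lipid-associated macrophage (0.35 to 1.80) it was CD45 negative lean 3 (0.0563), or CD45 positive lean 1 (0.135) or obese 2 (0.0509). For perivascular macrophage (1.10 to 2.96) it was CD45 positive lean 1 (0.0815). For mitochondrially encoded transcripts (0.13 to 0.59) it was CD45 negative lean 1 (0.198), obese 1 (0.0551) or obese 3 (0.133), or CD45 positive lean 1 (0.237), lean 2 (0.206) or obese 3 (0.144). For progenitor markers (-4.52 to -1.27) it was CD45 negative lean 1 (0.0539) or CD45 positive lean 2 (0.0587, median -1.27). For blood endothelial markers (0.26 to 2.05) it was CD45 negative lean 1 (0.0652), lean 3 (0.109), obese 1 (0.066) or obese 3 (0.196), or CD45 positive lean 1 (0.352) or obese 1 (0.111). For cDC1 markers (0.45 to 2.31) it was CD45 negative lean 1 (0.189), or CD45 positive lean 1 (0.134), lean 3 (0.0558) or obese 3 (0.104). For cDC2 markers (1.00 to 2.96) it was CD45 negative lean 1 (0.0614) or CD45 positive lean 1 (0.0815). Medians also moved without ending the call: lipid-associated macrophage 1.80 without CD45 positive lean 3, perivascular macrophage 1.10 without CD45 negative lean 1, mitochondrial 0.40 without CD45 negative obese 2 and 0.59 without CD45 positive lean 3. Blood endothelial markers were at 0.89 without CD45 negative lean 2, 1.22 without obese 2, 2.05 without CD45 positive lean 3 and 0.88 without obese 2, and cDC1 markers at 2.20 without CD45 negative obese 1 and 2.31 without CD45 positive lean 2. The other 5 held without each library in turn, with monocyte markers at 1.49 and MHC class II at 0.81 and macrophage markers at 1.28 without CD45 negative lean 1, and lysosome at 0.33 without CD45 positive lean 1 and 1.06 without lean 3.

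The first pattern weighed is the rise of NNMT and PLA2G2A in mural-like cells of obese donors. For NNMT, free RNA of progenitor-like cells, scaled by their markers, predicted less than was measured (median log2 of measured over predicted 1.81 over 3 obese libraries), and blood endothelial-like cells far less (6.97), which argues against both as the whole cause. From progenitor-like cells NNMT would need a leak of 9.79% to 18.7% in obese libraries, and 8 or 9 of the 10 markers lay below that in each, the exceptions being the collagen genes COL1A2 and COL3A1. For PLA2G2A, expression in mural-like cells and RNA of progenitor-like cells cannot be told apart: obese libraries measured about what that RNA predicted (-0.07), while lean libraries had 0 UMIs where 12.4 were predicted by the median marker and 4.23 by the lowest (exact Poisson p = 0.0146), a shortfall that rests on few UMIs. That p covers counting error only, not the spread of the leak between markers and donors. In blood endothelial-like cells of obese 1, 2 and 3, PLA2G2A was at 15.4, 7.8 and 6.6 CPM. Progenitor-like RNA predicted 17.1, 7.3 and 11.2 CPM there. Lean 1, 2 and 3 had 1.8, 0 and 0 CPM, where 1.4, 3.2 and 2.9 were predicted. A change of NNMT with obesity may be biological, but it stays a hypothesis, since keeping doublets ended its call (1.34, adjusted p = 0.103).

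The second pattern is the lower cytotoxicity list in monocyte-like cells of obese donors. It did not rest on the lean library with the fewest such cells, since without it the adjusted p was 2.81e-07. Free RNA of lymphocytes may be the cause: dendritic-like cells, which should lack these transcripts, had a median log2 change of -1.20 on the same members, against -1.30 in monocyte-like cells. Summed levels in lean and obese libraries were 150 ± 97.2 and 74.2 ± 49.7 CPM in dendritic-like and 72.9 ± 17.9 and 39.3 ± 19.7 CPM in B-like cells (SD, n = 3 and 3), and overlapped in both classes, unlike in monocyte-like cells. A change within monocytes stays open and untested.

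The third pattern is the higher interferon response list in progenitor-like cells of obese donors. Leaving out each of 6 libraries gave an adjusted p of at most 0.000111, which argues against 1 donor as the cause. RNA of the 4 other classes could supply at most 2.45% of the list's summed level. That summed level, dominated by a few abundant members, was 391, 683 and 735 CPM in lean 1, 2 and 3 and 702 to 745 CPM in obese libraries, so its difference came mostly from lean 1, although the list's call did not. A biological change with obesity is consistent with these tests but remains a hypothesis found on the same data, and the call was lost with an estimated correlation (adjusted p = 0.655).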

How the results depend on the processing

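Unnamed clusters given the class of their best list, and T-like cells without a heat-shock cluster, were alternatives chosen after the data were examined. Over all alternatives, 245 named gene results gave 4039 values: 3853 kept direction and side of the threshold, 151 passed newly, 15 no longer passed and 20 reversed. The 107 list calls gave 1288 values: 954 kept, 334 no longer passed, none reversed. The CD45 comparison called 12562 genes with a replicate block, 12837 with DESeq2, 15851 with no low-count filter and 12642 to 13271 with 1 library left out. Macrophage-like cells had as few as 135044 UMIs in a library and B-like cells 170308. The causes of the changes given here were not tested, except that leaving out libraries or cells also leaves fewer samples.

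Numbers of genes past the threshold moved as follows. DESeq2 gave 22 in CD45 negative and 106 in CD45 positive libraries, 28 in progenitor-like, 6 in blood endothelial-like, 5 in mural-like, 3 in macrophage-like, 2 in monocyte-like, 11 in dendritic-like, 33 in T-like, 13 in NK-like and 2 in B-like cells, 6 for the interaction and 5 in CD45 negative macrophage-like cells. No low-count filter gave 78 in blood endothelial-like, 46 in mural-like, 36 in macrophage-like, 112 in monocyte-like, 128 in dendritic-like, 150 in T-like, 152 in NK-like, 33 in B-like and 51 in CD45 negative macrophage-like cells. A replicate block, which within a fraction pairs lean and obese donors by number only, gave 1 in mural-like, 43 in macrophage-like, 8 in monocyte-like, 1 in dendritic-like, 1 in T-like, 2 in NK-like and 3 in B-like cells. At least 50 cells per library gave 2 in macrophage-like, 3 in monocyte-like, 1 in dendritic-like and 0 in B-like cells. Leiden resolution 2 gave 6 in macrophage-like, 12 in NK-like and 2 in CD45 negative macrophage-like cells. Doublets kept gave 1 in mural-like cells. In NK-like cells, at most 10% mitochondrial UMIs gave 2, principal components centred per library 2, and unnamed clusters given the class of their best list 12. The same reassignment gave 0 in monocyte-like cells.

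Leaving out 1 library gave 0 to 2 genes in CD45 negative libraries, 0 to 1 in progenitor-like, 0 to 6 in blood endothelial-like, 0 to 3 in mural-like, 2 to 4 in macrophage-like, 0 to 5 in monocyte-like, 0 to 2 in dendritic-like, T-like and NK-like, and 0 to 4 in B-like cells, 0 to 1 for the interaction and 1 to 2 in CD45 negative macrophage-like cells. Lists past the threshold numbered 4 to 9 in progenitor-like, 2 to 6 in blood endothelial-like and in mural-like, 5 to 10 in monocyte-like, 0 to 6 in dendritic-like, 3 to 11 in T-like, 5 to 8 in NK-like and 0 to 3 in B-like cells, 8 to 16 for the interaction and 6 to 11 in CD45 negative macrophage-like cells. Macrophage-like cells of CD45 positive libraries had 2 lean libraries, so only their fits without an obese library are counted here. Their lists fell to 0 without obese 2.

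With an estimated correlation, 0 lists passed in each of the 14 comparisons. With fry 39 passed for CD45, 1 in blood endothelial-like cells, 1 in T-like cells and 0 in each other comparison. A replicate block gave 23 lists in CD45 positive libraries, 7 in blood endothelial-like, 3 in dendritic-like, 1 in B-like and 11 in CD45 negative macrophage-like cells.

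Differences in share (obese minus lean, in percentage points) that reversed were, with components centred per library, progenitor-like 0.616, unnamed CD45 negative -1.59, CD45 positive NK-like -2.95 and T-like -1.85. NK-like cells also reversed at Leiden resolution 2 (-6.93) and with unnamed clusters reassigned (-11.0), and T-like cells with at most 10% mitochondrial UMIs (-0.067), at least 1000 UMIs (-0.470) and unnamed clusters reassigned (-1.77). CD45 positive macrophage-like cells reached 0.0439 at Leiden resolution 2. With 1 library left out, differences ran from -1.25 to 0.787 in CD45 negative NK-like, -1.76 to 5.42 in CD45 positive NK-like, -12.6 to 16.0 in T-like and -1.79 to 0.0610 in CD45 positive macrophage-like cells.

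Genes whose log2 change reversed were APOC1 (-0.011 with centred components, -0.38 at Leiden resolution 2) and CXCL1 (-0.39 at resolution 2) in macrophage-like cells, PTX3 in monocyte-like cells (0.12 with at least 50 cells), RGS1 in NK-like cells (-0.048 centred, -0.003 reassigned), and LIPA (0.32), MRC1 (0.042) and CTSD (0.23) at resolution 2 in CD45 negative macrophage-like cells. With 1 library left out, changes ran from -0.005 to 0.64 for CD36 in CD45 negative libraries, -0.027 to 0.95 for TBX1 in progenitor-like, -0.52 to 0.10 for SEMA3G in blood endothelial-like, -0.18 to 0.72 for NFKBIZ and -0.077 to 1.84 for CCL2 in mural-like, -0.99 to 0.12 for PTX3 in monocyte-like, -0.028 to 0.30 for RGS1 in NK-like, -0.026 to 0.35 for KLF2 in B-like, and -2.65 to 0.52 for FABP4 and -1.41 to 0.35 for LIPA in CD45 negative macrophage-like cells.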

Other observations

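The splits of samples were counted after the results were seen. The macrophage-like class of the CD45 negative libraries was added after the data were examined. In its cells, type 2 conventional dendritic cell markers had 5 of 5 members above 0 in obese donors (median 0.76, adjusted p = 0.00367; adjusted p = 0.565 with an estimated correlation), held without each library in turn (median 1.25 without obese 1), and 2 passed adjusted over the list alone. At Leiden resolution 2 this class parts into a macrophage cluster and a cluster led by IL1B whose best list is that of type 2 dendritic cells. The latter took 22.1% ± 9.18 of the class in lean and 34.9% ± 2.2 in obese libraries (exact permutation p = 0.1, n = 3 and 3), so the change can follow these shares. CD1E, a lipid antigen presenting molecule of dendritic cells, was at 16.6 ± 9.93 CPM in lean and 67.7 ± 39.2 CPM in obese libraries (log2 2.02 ± 0.50; SE and SD, n = 3 and 3, adjusted p = 0.999), and the chemokine gene CCL2 at 310 ± 66.1 and 98.1 ± 54.5 CPM. Of 6042 genes 1 passed, an HLA gene, and 2 without lean 1. Of 24 lists 7 passed, and 11 without lean 3.

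Shares of some clusters follow, each with a p no lower than the floor of its test and none past adjustment. A CD4 T-like cluster with CCR6 and CCR7 was 4.16% ± 0.728 of lean and 8.11% ± 1.19 of obese CD45 positive cells (SD, n = 3 and 3, exact permutation p = 0.1). Another CD4 T-like cluster was 16.6% ± 8.86 of lean and 5.86% ± 1.05 of obese T-like cells (exact permutation p = 0.1, n = 3 and 3), and 2635 of its 3938 cells came from 1 library. Among progenitor-like cells, a cluster led by MYOC was 10.9% ± 6.61 in lean and 4.65% ± 2.51 in obese libraries (exact permutation p = 0.1, n = 3 and 3). An unnamed CD45 positive cluster of 5728 cells, led by FGFBP2 and between CD8 T and NK markers, was 20.3% ± 13 of lean and 6.97% ± 4.31 of obese libraries (exact permutation p = 0.3, n = 3 and 3).

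For CD45 positive against negative, 1 of 100 splits of the 12 libraries, the real one, gave 12685 genes, and the highest other gave 0. Every other split mixes both fractions in both arms, so the difference of the sort widens its spread and lowers its calls. The count of genes therefore cannot exclude chance by itself. The 24 lists of the real split were reached by 15 of the 100 splits (highest other 31), so chance is not excluded for the number of lists. The other splits mix the fractions here too, so this count cannot show chance either. By fry, all 24 lists held. Donors pair the libraries, and of the other 31 splits that part all 6 pairs 1 gave 2093 genes (with 24 lists) and the others 0, while the most lists, 26, came from a split with 0 genes.

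For 3 against 3, 10 splits cannot give a share under 0.05. In genes, the real value and the highest other split were 0 and 1 in CD45 negative libraries, 0 and 1 in CD45 positive libraries, 0 and 2 in progenitor-like, 0 and 1 in blood endothelial-like, 2 and 4 in mural-like, 1 and 2 in monocyte-like, 0 and 4 in dendritic-like, 0 and 1 in T-like, 1 and 7 in NK-like and 1 and 1 in B-like cells, 0 and 0 for the interaction and 1 and 1 in CD45 negative macrophage-like cells. In lists, they were 10 and 24 in CD45 negative libraries, 14 and 19 in CD45 positive libraries, 4 and 8 in progenitor-like, 2 and 9 in blood endothelial-like, 4 and 8 in mural-like, 6 and 12 in monocyte-like, 1 and 10 in dendritic-like, 7 and 10 in T-like, 9 and 9 in NK-like and 2 and 3 in B-like cells, 13 and 24 for the interaction and 7 and 8 in CD45 negative macrophage-like cells. Splits with as many, the real one included, numbered 2 to 10 in genes (4 in monocyte-like cells). In lists they numbered 5, 7, 7, 9, 5, 5, 9, 2, 2, 4, 6 and 5, in the order given. Macrophage-like cells of CD45 positive libraries, at 2 against 3, have no such count.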
